A study of Rattus norvegicus with 15 samples.

How the data were processed

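Liver RNA from 15 Sprague Dawley rats, an outbred laboratory strain, was profiled by RNA sequencing after 20 weeks of feeding. Total RNA was extracted with a Qiagen RNeasy kit and libraries were prepared by Novogene, per the labels' protocols. Libraries were grouped by their titles into control (chow), D4 and D5, with 5 rats in each group. A short code given with each sample carries a diet number that differs from the diet in its title (D5 on the controls, D3 on the D4 rats, D4 on the D5 rats). Titles and treatment labels match each other, so they set the groups, and the codes served only to tie each column of values to its rat. No rat number occurs in more than 1 group, and the labels name no batch, sex or sampling time. The labels number the rats separately, so each library was taken as 1 animal, and p-values set group differences against the spread between these animals.

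The deposited values are estimated counts per gene, 1 column per rat, not scaled between libraries. Of all values, 33.2% are not whole numbers. The submitters' processing notes name FastQC 0.11.9, MultiQC 1.8, cutadapt 2.10, Salmon 1.3.0 and DESeq2 1.24.0 and the genome build mRatBN7.2, with no role or order. The step from transcripts to genes, the annotation release, the read length and the strand setting are not given in the sources used here. Salmon divides reads that match several transcripts by probability, so counts of near-identical genes are uncertain. Each library held 17066763 to 23629224 estimated reads.

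The values were rounded to whole numbers before testing. The table listed 30208 gene identifiers, of which 8589 were at 0 in every library. After edgeR's filterByExpr by group, 14279 identifiers were tested. Libraries were scaled by the trimmed mean of M-values (TMM), and groups were compared with edgeR 4.0.16 quasi-likelihood tests (glmQLFit, glmQLFTest) in R 4.3.3, with all 15 libraries in 1 fit and group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 2-fold counts also required an absolute log2 fold change of at least 1. Standard errors of fold changes were taken from the F statistic. Log2 CPM values (CPM: counts of a gene scaled to a common library size) for principal components, correlations and response scores used a prior count of 2. Library measures were compared with two-sided exact permutation tests over all 252 regroupings of 10 libraries, the smallest p of which is 0.00794, with Benjamini-Hochberg adjustment over 12 tests.

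The table pairs no identifier with a gene name, and the reference table at hand (assembly GRCr8) matched 0 of the 30208 identifiers. The 35 gene lists fixed for this tissue and treatment therefore were not tested, and gene positions, GC content and length are not used here. The rule for genes named in the text took, per comparison, the largest rises and falls among called genes with an average log2 CPM of at least 1 and no overlap between the groups, together with a condition on the gene symbol. Without names that condition was dropped, and the identifiers printed were limited to 2 that rose and 2 that fell: the first in D4 and the first further one in D5. The tests, groups, gene lists, naming rule and most alternatives were fixed before the data were examined.

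Alternatives tried were relative log expression scaling, total-count scaling, the DESeq2 1.42.0 Wald test, limma 3.58.1 voom with sample weights, no filter on low counts, at least 1 CPM in at least 5 libraries, only the 2 groups compared, 1 surrogate variable from svaseq (sva 3.50.0), and leaving out each rat in turn. The surrogate variable was estimated from the filtered, rounded counts without scaling between libraries. Leaving out D4 R52 and D5 R27 together was added after seeing the data. Because D4 and D5 share their controls, the overlap of their calls was set beside 20 simulations of unchanged groups, with 1 simulated control group for both diets. It was also set beside the overlap of independent lists and beside 20 assignments with the controls split 2 against 3. To count other groupings, 100 of the 126 splits of each 10 libraries were drawn. Pairs of libraries in a group were checked for duplication by a chi-square of their counts, which lay between 26.0 and 174.1 per gene.

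The edgeR fit was tested on simulated counts. Each gene was drawn at its mean level in controls in every group, with the spread of each group and the real library sizes. Genes were drawn independently of each other. For D4 against control it recovered 1.02% of genes changed 1.5-fold, 47.6% of those changed 2-fold and 93.8% of those changed 4-fold, with 196, 189 and 195 genes changed among 13722, 13688 and 13730 tested. For D5 against D4 the shares were 0% (of 195 among 13698), 59.6% (of 193 among 13705) and 93.8% (of 195 among 13705). Recovery after Benjamini-Hochberg adjustment depends on the share of genes changed, which here was far below the 25.2% called in D4 against control. The shares recovered therefore do not give the recovery in that comparison. Between 0 and 21 unchanged genes were called per simulation. In D5 against D4 they numbered 13 at 2-fold and 21 at 4-fold, a larger share of the calls than the 0.05 aimed at.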

Results

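Rats were fed chow or 1 of 2 diets meant to model metabolic dysfunction-associated steatotic liver disease (MASLD), and liver RNA was sequenced after 20 weeks. Diet 4 (D4) held 2% cholesterol, and diet 5 (D5) held 2% cholesterol with 0.1% cholic acid, a primary bile acid. Rats on both diets also drank a sugar solution (110 g per litre, 45% glucose and 55% fructose), so each comparison with chow covers the drink as well as the food. Each group had 5 rats. Total estimated counts per liver were 17066763 to 22728127 in controls, 19816253 to 23629224 in D4 and 19496043 to 22490253 in D5, and no difference in totals passed a two-sided exact permutation test (lowest p = 0.0873, n = 5 per group).

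Libraries from both diets held more identifiers with a count above 0 than control libraries. A mean of 16958 ± 68.5 identifiers (SD, n = 5) had a count above 0 in controls, 17820 ± 437 in D4 and 17781 ± 331 in D5. Each diet differed from control (exact permutation p = 0.00794, the smallest this design allows, adjusted p = 0.0238), and D5 differed from D4 by less than the spread between rats (exact permutation p = 0.897). The most abundant gene was the same in all 15 libraries, and its share of the counts was 8.99% ± 0.793 (SD, n = 5) in controls, 6.04% ± 0.576 in D4 and 6.32% ± 0.814 in D5. That share was lower in each diet than in control (exact permutation p = 0.00794, adjusted p = 0.0238) and did not separate the diets (exact permutation p = 0.563).

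The first principal component of log2 CPM carried 41.9% of the variance and separated every control (-76.3 to -43.5) from every diet liver (-18.7 to 54.8). D5 livers (7.70 to 42.3) lay within the range of the D4 livers. D4 rat R52 was the diet liver nearest the controls, at -18.7. Spearman correlations across genes had a median of 0.977 between controls, 0.965 between D4 livers and 0.968 between D5 livers. The median was 0.969 between D4 and D5 livers and 0.944 between either diet and control.

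**Figure D1:**
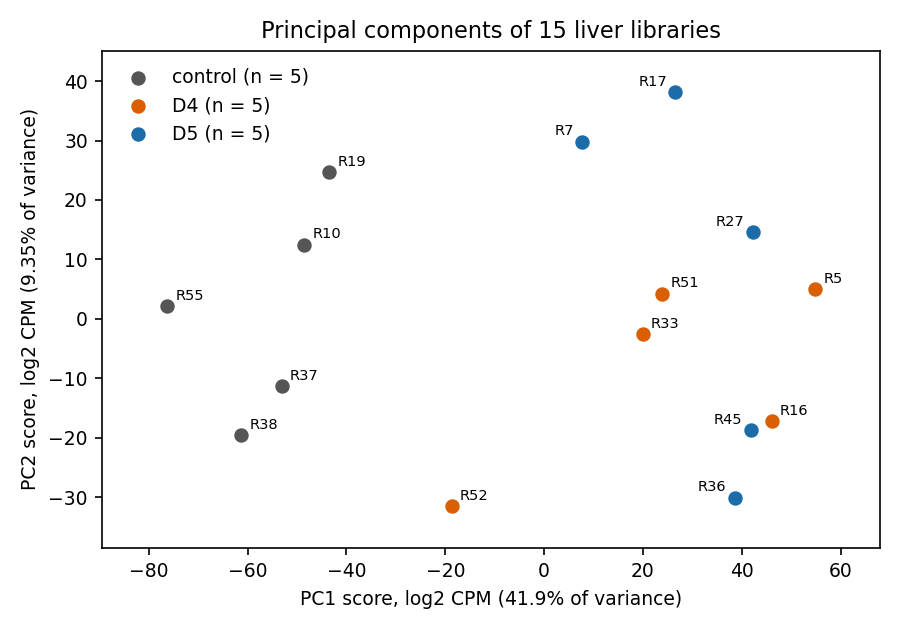
Scores of the 15 livers on the first 2 principal components of log2 CPM over 14279 genes, 1 point per rat, coloured by group and marked with the rat's number. Controls lie between -76.3 and -43.5 on the first component, and the D4 and D5 livers overlap between 7.70 and 42.3.

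The comparison of D4 with control asked what the cholesterol diet and sugar drink change in the liver. Genes called higher in D4 livers were mostly of low abundance in chow-fed livers and rose by more than 2-fold. Genes called lower were mostly more abundant and fell by less. Of 14279 genes tested, 3597 (25.2%) changed in edgeR's quasi-likelihood test, 2010 higher and 1587 lower. The 2010 higher genes had a median log2 fold change of 1.35 and a median level of 3.13 CPM in controls. The 1587 lower genes had a median of -0.54 and a median control level of 45.9 CPM. The median SE was 0.319 for the higher and 0.139 for the lower genes. A gene with a larger SE must change more to be called, so the threshold may account for part of the contrast in size. At least 2-fold changes were found in 1356 higher and 217 lower genes, at least 4-fold changes in 436 and 30, and at least 16-fold changes in 38 and 3. Among the higher genes, 13 had at most 3 counts over all 5 controls, and 10 of these were detected in all 5 D4 livers, so their fitted fold changes are not measured sizes. The 5 D4 and 5 control livers did not overlap for 2044 genes (14.3%), where chance gives 0.794%.

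The gene with the largest rise by the naming rule, ENSRNOG00000012660, was 7.78 ± 1.89 higher on the log2 scale (SE, edgeR adjusted p = 0.00841). It was higher in 5 of 5 rats than in any control, which the rule required of every gene it took. Its D4 level of 16.3 ± 31.3 CPM (SD, n = 5) ranged from 0.301 to 72.1, against 0.0652 ± 0.0711 in controls (at most 0.169). Without rat R5, which held the highest level, the log2 fold change was 4.98, and with limma voom and sample weights it was 4.53 (adjusted p = 0.102). Over 18 alternatives its adjusted p ran from 4.06e-06 to 0.642, and 16 passed. ENSRNOG00000020989 had the largest fall by the same rule, from 71.0 ± 19.5 to 6.51 ± 2.23 CPM (log2 fold change -3.44 ± 0.285, SE, edgeR adjusted p = 2.04e-05). The rule likewise required that it be lower in 5 of 5 rats than in any control. The identifiers are not paired with gene names in the files used here.

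Scaling by total counts alone shifted the median log2 fold change of all genes from 0.0088 to 0.23, and the split of called genes became 3164 higher and 626 lower. With 1 surrogate variable in the model 49 genes passed (26 higher, 23 lower), of which 42 were among the 3597. The variable itself differed with the diet, so it takes up part of the difference tested.

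**Figure D2:**
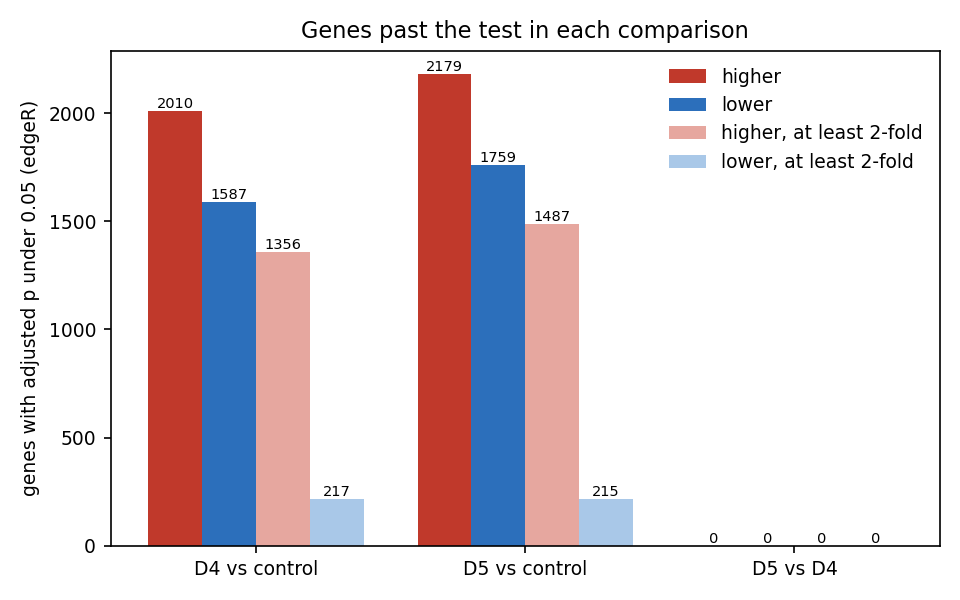
Number of genes with an edgeR adjusted p under 0.05 in each comparison (vertical axis, from 0), split into higher and lower genes and into those changed at least 2-fold. The diets gave 3597 and 3938 genes against control, with more higher than lower genes at 2-fold, and D5 against D4 gave 0.

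The comparison of D5 with control asked what the diet with cholesterol and cholic acid changes. Again many of the called genes were of low abundance and rose, and more abundant genes were called with smaller falls. In D5 livers 3938 genes (27.6%) changed, 2179 higher and 1759 lower. Higher genes had a median log2 fold change of 1.37 from a median control level of 2.93 CPM, and lower genes had a median of -0.51 from 42.8 CPM. Their median SEs were 0.324 and 0.134, so the same limit of the threshold holds here. Changes of at least 2-fold were found in 1487 higher and 215 lower genes, of at least 4-fold in 490 and 40, and of at least 16-fold in 32 and 2. Among the higher genes, 12 had at most 3 counts over the controls, and 10 of them were detected in all 5 D5 livers. The groups did not overlap for 2733 genes (19.1%, chance 0.794%).

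ENSRNOG00000009919 rose from 0.909 ± 1.64 CPM in controls (SD, n = 5) to 53.4 ± 30.4 in D5, a log2 fold change of 5.89 ± 1.11 (SE, edgeR adjusted p = 0.00222). It was higher in 5 of 5 D5 rats than in any control, as the naming rule required. In D4 the same gene stood at 34.6 ± 32.1 CPM (log2 fold change 5.27 ± 1.09, adjusted p = 0.00376). One control, R37, held 3.83 CPM, more than D4 rat R52 (1.74 CPM), so D4 and control overlapped. Without R37 the log2 fold changes were 8.22 in D5 and 7.60 in D4. ENSRNOG00000071167 fell from 9.47 ± 2.60 to 0.625 ± 0.244 CPM in D5 (log2 fold change -3.91 ± 0.295, edgeR adjusted p = 9.91e-06), and its D4 level was 1.2 ± 0.36 CPM (-2.93 ± 0.277, adjusted p = 5.89e-05). ENSRNOG00000020989 also fell in D5, to 7.82 ± 2.78 CPM (-3.18 ± 0.281, adjusted p = 2.34e-05). ENSRNOG00000012660, called in D4, was at 2.27 ± 3.26 CPM in D5 and did not pass the edgeR test there (log2 fold change 4.92 ± 1.99, adjusted p = 0.078). Without D5 rat R36, which held the highest D5 level (7.95 CPM), that log2 fold change was 3.51. The D5 against D4 difference of ENSRNOG00000012660 was not past the test either (-2.85 ± 1.25, edgeR adjusted p = 1).

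With total-count scaling the median log2 fold change of all genes was 0.23 in place of -0.0046, and the split was 3144 higher and 506 lower. With 1 surrogate variable, which takes up part of the diet difference as in D4, 62 genes passed (27 higher, 35 lower), 55 of them among the 3938.

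**Figure D3:**
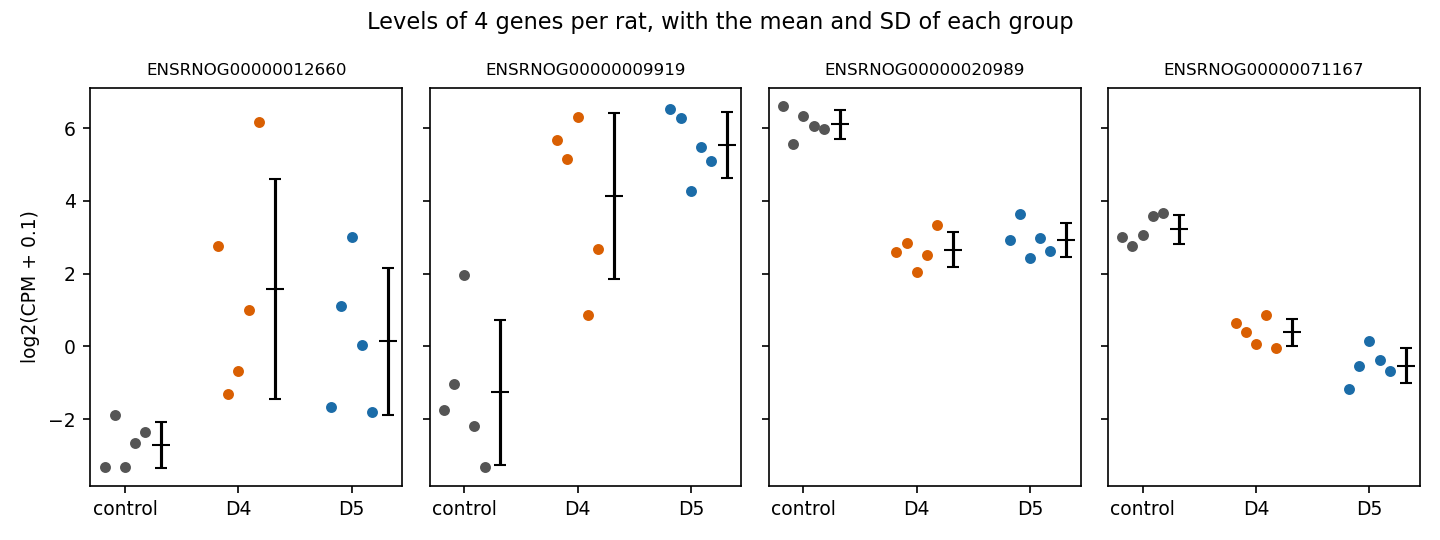
Levels of the 4 printed genes in each rat, as log2(CPM + 0.1), with 5 points per group and the group mean and SD of these log values as black bars. ENSRNOG00000020989 and ENSRNOG00000071167 are lower in every D4 and D5 rat than in every control. The naming rule required this of the first in D4 and of the second in D5. ENSRNOG00000012660 spans a wide range among D4 rats, 0.301 to 72.1 CPM.

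The comparison of D5 with D4 asked what cholic acid adds to the cholesterol diet, and it is also the test of whether the 2 diet responses differ. No gene set the livers of the 2 diets apart: edgeR called 0 of 14279 genes, with 400 at an unadjusted p under 0.05 where chance alone would give 714. The lowest adjusted p was 1. DESeq2 and limma voom also called 0 genes, with 573 of 21559 and 583 of 14279 genes at an unadjusted p under 0.05. The livers of the 2 diets did not overlap for 63 genes (0.441%), below the chance share of 0.794%. The 95% interval of the D5 to D4 ratio lay within 2-fold either way for 11464 genes (80.3%), with a median half-width of 0.40 on the log2 scale. Differences of at least 2-fold therefore were not excluded for the remaining genes. In counts simulated at control levels, with genes drawn independently, 59.6% of 2-fold and 0% of 1.5-fold changes were recovered. Few genes were changed there (193 of 13705 at 2-fold, 195 of 13698 at 1.5-fold), and recovery depends on that share. Recovery at the levels of the diet livers was not simulated.

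Both comparisons called 2942 genes in the same direction, 1689 higher and 1253 lower, and 0 in opposite directions. That is 81.8% of the D4 calls and 74.7% of the D5 calls. Independent lists of these sizes would share 307 higher and 195 lower genes. Simulated diet groups without any effect, set against 1 simulated control group, shared at most 1. With no effect hardly any gene is called, so this does not show how much the shared controls add to the 2942. With the controls divided so that each diet had its own 2 or 3, the mean overlap was 801 genes (283 to 1172), from 1816 D4 and 2022 D5 calls on average. Across genes, which are not independent replicates, the log2 fold changes of the 2 diets correlated at 0.93, against 0.471 simulated from the shared controls alone, and at a mean of 0.717 (0.653 to 0.765) with the controls split. Of all genes 87.8% had the same sign in both, against 65.9% simulated. The covariance was 0.593 against a simulated 0.044, a difference of 0.548. With the controls split its mean was 0.645, so the covariance, unlike the correlation, did not fall. Among the 2942 shared genes the median absolute log2 change was 0.95 in D4 and 0.93 in D5, and 50.7% changed more in D5. For 2325 of them (79%) the 95% interval of the D5 to D4 ratio lay within 2-fold.

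**Figure D4:**
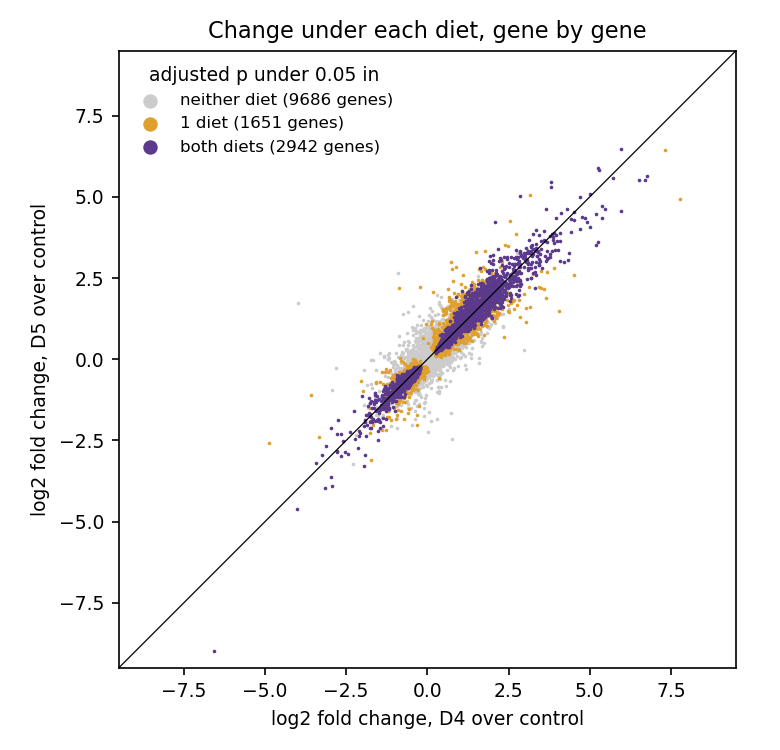
Log2 fold change over control of each of 14279 genes in D4 (horizontal) and D5 (vertical), 1 point per gene, coloured by whether the edgeR adjusted p was under 0.05 in both diets, 1 diet or neither, with the line of equal change. Points called in both diets (2942 genes) lie along the line, and the correlation across genes is 0.93, against 0.471 simulated from the shared controls alone and 0.717 with the controls split.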

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

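The comparison of R52 with the control scores and the count of R27 genes outside the range of the other livers were chosen only after the result was seen, as were the check of the R52 shares under total-count scaling, the abundance filter on the midpoint of control and diet, the computed mixtures, and the comparison of the highest D5 against D4 split with the mean rise and the scaling factors. The other tests were set before. A search of 45 sets of 5 libraries for a value far from the others found 3, and chance gives about 1 in 20.

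D5 rat R27 stood far from the other D5 rats in 2 ways. Whole numbers made up 84.4% of its values, against 59.9% to 66.3% in the other D5 rats, and 50 of its genes lay outside the range of the other 14 livers by over 2 on the log2 scale, 49 of them below, against at most 17 in any other library. That the values of R27 were made differently from the others is a candidate explanation, which the 50 genes cannot support, since they are part of what set R27 apart. Its depth (20581503 counts) lay inside the range of the other D5 rats, and nothing in the sources used here tells a difference in quantification from one in the reads or in the animal. Without R27, D5 against control called 3181 genes in place of 3938, no larger a drop than without R36 (3108) or R45 (3036).

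D4 rat R5 had 17 genes outside the range of the other 14 livers, all above it, against 0 to 2 in the other D4 rats.

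D4 rat R52 lay between the controls and the other diet livers. A response score was computed as the slope of a liver's log2 differences from control on those of D5, over genes called in D5 (0 is a control, 1 the mean D5 liver). R52 scored 0.46, above the highest control (0.149) by more than the SD of the control scores (0.152). That argues against a control liver under a wrong label, but it repeats the place above the controls that prompted the check. With all libraries thinned to the smallest total (17066669) the other 4 D4 rats still scored at least 0.42 higher than R52, which argues against depth. In R52 the share of the D5 response was 0.231 in genes that rose and 0.657 in genes that fell, a difference of -0.425. The other D4 rats lay between -0.102 and 0.0849, and 180 mixtures computed from a control and another D4 liver between -0.208 and 0.228. With total-count scaling R52 (-0.574) lay only just outside the other D4 rats (-0.507 in R51 to 0.559 in R16). Such a difference was not particular to R52: D5 rat R7 reached 0.536 in genes that rose and 0.855 in genes that fell. The difference in R7 (-0.319) also lay outside these mixtures, and with total-count scaling (-0.764) it lay beyond R52. Mixtures with a liver like R7 were not computed, so the values argue against mixing with control RNA only for the livers used. A smaller response of R52 to the diet, mainly in the genes that rose, remains open and untested.

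More genes rose than fell by at least 2-fold, at ratios of 6.25 in D4 and 6.92 in D5. Under relative log expression and total-count scaling the lowest ratio over both diets was 6.17, and total-count scaling gave 14.9 in D4 and 15.9 in D5. These scalings could hardly lower the ratio, so they do not exclude scaling as a cause. Relative log expression scaling left the median log2 fold change in D4 near that under TMM (0.0045 against 0.0088), and total-count scaling raised it to 0.23. With 1 surrogate variable, which itself differed with the diet, the ratios were 1.16 in D4 and 0.963 in D5. The ratios were lower, but above 1.5, among 7781 genes with a mean of at least 10 CPM over all livers (3.09 in D4 and 3.39 in D5), a filter that favours genes that rose, and among genes whose midpoint of control and diet was at least 10 CPM (2.22 and 2.55), which argues against low counts as the whole cause. GC content and gene length were not tested, because the identifiers could not be matched to a reference, and neither was a change in the cell types of the liver. A response of the liver to the diets, including such a change, may underlie the excess and remains a hypothesis.

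Other splits of the same 10 livers were refitted, 100 of 126 per comparison. For D4 against control only the true split (1 of 100) gave as many as 3597 genes. The highest other split gave 2865 and exchanged D4 R52 with control R19. For D5 against control only the true split (1 of 100) reached 3938, and the highest other gave 4. Chance is therefore unlikely for both counts, at the smallest share that 100 drawn splits can give. The rest of the 126 splits were not fitted. For D5 against D4, 78 of 100 splits gave at least the 400 genes at an unadjusted p under 0.05, so chance is not excluded. The highest gave 2227 such genes and 167 past the adjusted threshold, by setting D4 R16 and R5 with D5 R27, R36 and R45 against the other 5 diet rats, which may reflect a structure among these livers other than the assigned diet. Those 5 rats had the largest mean rise over the genes called higher in both diets (1.61 to 1.74 on the log2 scale, against 0.655 to 1.42 in the other 5) and also the largest TMM factors of the diet rats (1.07 to 1.185, against 0.9398 to 1.044), so the source of the split stays open. It was the highest of 100 splits, of which 4 called any gene.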

How the results depend on the processing

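Of the alternatives given here, only leaving out D4 R52 and D5 R27 together was chosen after the result was seen. Under relative log expression or total-count scaling, DESeq2, limma voom, either other filter and a fit of only the 2 groups, D4 against control called 2957 to 4342 genes (3597 as reported), D5 against control 3523 to 4770 (3938) and both 2470 to 3586 (2942), and D5 against D4 called 0 each time. The counts at 2-fold were 1343 to 1992 in D4 (1573) and 1511 to 2035 in D5 (1702). Leaving out 1 rat gave 2652 (without D4 R16) to 4387 (without R52), 3036 to 3974, and 2238 to 3168, and 0 for D5 against D4. Without R52 and R27 the counts were 4286, 3533, 3033 and 0. Total-count scaling kept 73.3% of the D4 calls and 68.2% of the D5 calls and changed the split: called genes were 83.5% higher in D4 and 86.1% in D5, against 55.9% and 55.3%. With 1 surrogate variable the calls fell to 49 in D4 (41 at 2-fold) and 62 in D5 (53 at 2-fold), and the excess of higher genes was lost: at 2-fold 22 were higher and 19 lower in D4, and 26 and 27 in D5. That variable itself differed with the diet (0.182 to 0.384 in controls, -0.528 to 0.194 in diet livers, with R52 alone in the control range), so it takes up part of the difference tested. With the controls split 2 against 3 the overlap was 801, with fewer controls per comparison. No printed gene changed sign. Of the 4 printed genes, the calls of ENSRNOG00000012660 in D4 and of ENSRNOG00000009919 in both diets were lost with the surrogate variable. The log2 fold change of the first fell to 2.22 ± 1.99 (from 7.78 ± 1.89), while that of the second stayed at 5.26 ± 2.05 in D4 and 5.88 ± 2.26 in D5 with a larger SE (from 1.09 and 1.11). The first was also lost with limma voom, and ENSRNOG00000012660 passed in D5 with DESeq2. The planned gene list tests (camera, fry and a prior count of 0.5) were not run, because no identifier had a name. Depth limits the fold changes of the 13 genes in D4 and 12 in D5 with at most 3 control counts.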

Other observations

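The check of rise and fall under total-count scaling and the count of nearly absent genes without R27 were chosen only after the result was seen.

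Some genes were nearly absent in 1 rat and clearly detected in another rat of the same group. With at most 1 count in at least 1 rat and at least 5 CPM in another, there were 14 such genes among the 5 controls, 7 among the D4 rats and 21 among the D5 rats (10 without R27). At least 2 rats stood on each side for 3, 4 and 1 of them.

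The diet rats differed in how far the shared response went. Over the 1689 genes called higher in both diets, the mean log2 rise above the control mean ran from 0.655 (D4 R52) and 1.02 (D5 R7) to 1.74 (D4 R16), and over the 1253 genes called lower the mean fall ran from 0.486 (R52) to 0.872 (D4 R5). The hypothesis that both follow a single graded response was tested across the 10 diet rats. Rise and fall correlated (Pearson r = 0.914, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = 0.939, permutation p = 0.00017; 1 relation tested). Without R52 and R7, farthest from the median rise, r was 0.816, and after taking out each diet's mean it was 0.928. With total-count scaling r was -0.0805. The relation was therefore seen with TMM and not with total-count scaling, and no other scaling was tried for it. A change of scaling factor moves the rise and the fall of a liver in opposite directions. TMM divides the counts of livers with a larger rise by a larger factor. Neither value decides the question, and a graded response cannot be told apart from the scaling.

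The spread between rats was also compared across the 3 groups. The mean root mean square distance of a liver from its group mean was 0.416 in controls, 0.448 in D4 and 0.442 in D5 on the log2 scale, and no difference passed (two-sided exact permutation p = 0.5, 0.325 and 0.873 for D4 with control, D5 with control and D5 with D4). The largest distances were those of D4 R5 (0.564) and D4 R52 (0.546).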
